A study of Mus musculus with 4 samples.

How the data were processed

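Genomic DNA of E14 cells, a mouse embryonic stem cell line, was analysed by methylation-assisted bisulfite sequencing (MAB-Seq) in 4 libraries. In the whole-genome protocol, DNA was sheared after enzymatic methylation, and 2 libraries of wild-type cells were made. In the reduced-representation protocol, DNA was cut with MspI, which cleaves at a CpG-containing site, and 1 library was made from cells with a control shRNA and 1 from cells with an shRNA against Tdg. Per the labels' protocols, DNA with a small amount of *E. coli* DNA added was incubated with the CpG methyltransferase M.SssI and this was repeated 3 times. Adapter-ligated DNA was treated with the enzyme again, fragments of 180 to 350 bp were recovered, and the bisulfite-converted DNA went through 15 PCR cycles. The *E. coli* DNA was not analysed here. M.SssI methylates the unmodified cytosines of CpGs. 5-Methylcytosine and 5-hydroxymethylcytosine resist bisulfite, so that in MAB-Seq a CpG cytosine read as thymine carried 5-formylcytosine or 5-carboxylcytosine, or escaped the enzyme. The level of a site is the share of reads that were converted.

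Per the submitters' processing notes, CASAVA 1.8, Bismark 0.10.1 and the mouse build mm9 were used. The rule by which sites were called, the filters and the number of reads per library are not given in the sources used here. Each deposited file listed single CpG positions of 1 library with 1 value per position, and what this value was differed between files. For the first whole-genome library and for both shRNA libraries, the deposited value was a percentage from 0 to 100. For the second whole-genome library, the deposited value was a p-value, at most 0.00997, and no level was given. The first whole-genome library listed the plus-strand cytosine of each CpG together with the 5 bases centred on it. The second library listed both strands. Both shRNA files marked every position as plus strand, yet 129 positions of the control shRNA library coincided with plus-strand and 172 with minus-strand positions of the second whole-genome library. The corresponding numbers for the Tdg shRNA library were 457 and 586. Both strands are therefore present in these 2 files, and the strand of a single position is unknown.

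The values were examined for what the authors had done to make them. Backgrounds of 0.1% to 10% were tried in steps of 0.1%. Of the deposited percentages of the first library, 100% equalled a fraction of 3 decimals from which a background of 3.0% had been subtracted and which had been divided by the remainder (tolerance 1e-06 of the last decimal). The next best background matched 22.6% of values. The same held for 100% of the values of the control shRNA library with 4 decimals and a background of 2.9%, and for 100% of those of the Tdg shRNA library with 3.3%. Adding the background back gave the uncorrected fraction. The deposited p-values of the second library were compared with upper tails of binomial distributions of up to 400 reads for backgrounds from 2% to 6%, of which 3.8% matched 99.8% of the p-values above 1e-07 and the next best matched 0%. With up to 20000 reads tried, 101128 sites, 99.97% of those with a p-value above 1e-07, matched exactly 1 combination of total and converted reads (relative tolerance 1e-08), and 27 matched more than 1. A tolerance of 1e-06 was tried first and left 14600 sites with more than 1 match. It was narrowed after this had been seen, because the p-values carry more digits. The most frequent p-value, 0.00538, was that of 3 converted reads among 10 and was shared by 12166 sites. These recovered reads are used below as the depth of the second library. They cover 85.3% of its sites and miss those with the smallest p-values, so levels drawn from them leave out the highest. No depth was recovered for the other libraries, whose depth is unknown.

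Sites were compared by exact position, and for whole-genome libraries by strand. Where strands were merged, a minus-strand position was assigned to the plus-strand cytosine of its CpG, and in the shRNA libraries adjacent positions were joined. Shares of sites are given with exact (Clopper-Pearson) 95% intervals, counts with exact Poisson intervals, ratios of 2 counts with the exact conditional binomial interval, and medians with intervals from order statistics. These intervals cover counting error only. They treat sites as independent, which neighbouring sites on the same reads are not, and PCR copies were not told apart. Each shRNA group had 1 library and the values of the 2 whole-genome libraries were in different units, so no p-value between groups was computed. The design fixed before the data were examined had assumed levels, counts or coverage in every file. Coverage minimums and tests per site on counts were therefore not run. One list was also moved along the chromosomes by a random 20 to 200 kb, 20 times. Of plus-strand sites of the second whole-genome library, 0.0135% to 0.0354% then coincided with a site of the first and 3.35% to 3.85% had one within 100 bp, and 1.16% to 1.98% of Tdg shRNA sites had a control site within 1 kb. Moved sites mostly leave CpGs and MspI fragments, so these values are no chance level among CpGs that could be listed, which needs the coverage of each library and was not computed. Site density per chromosome was taken up to the last position listed in any library.

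No genome or annotation of mm9 was used here. The planned comparison with all CpGs of the genome, the classes promoter, exon, intron and intergenic, the profile around transcription starts and the 15 gene lists fixed before the data were examined were therefore not run, and no gene is named. By the rule fixed for that case, the text gives the 5 windows of 10 kb with the most sites listed in both whole-genome libraries and the 5 with the largest gain and loss of sites between control and Tdg shRNA. Ties were broken by chromosome and position. Dense windows, defined after the data were seen, are the 12 windows of 10 kb with at least 50 sites in each whole-genome library. They do not depend on the shRNA libraries, but they do depend on the second whole-genome library, which also supplies the recovered depth. Coordinates are mm9 and counted from 1. Alternatives were a stricter threshold on the authors' value, autosomes only, merged strands, looser matching (10 or 100 bp) and leaving out each whole-genome library. Leaving out dense windows, using uncorrected fractions and limiting sites by level were added later.

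Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. The recovery steps were tested on simulated data. For p-values of 5978 simulated sites made with a background of 3.8%, the true reads were returned for 99.9% of sites. When a background that was wrong was assumed, 0 sites matched. The simulated depths stayed far below the largest recovered depth of 9406 reads, so recovery at the deepest sites was not tested. The backgrounds of 3.0%, 2.9% and 3.3% were each returned from 5000 simulated levels.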

Results

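MAB-Seq was used to locate 5-formylcytosine (5fC) and 5-carboxylcytosine (5caC), oxidation products of 5-methylcytosine, at single CpGs of mouse E14 embryonic stem cells. TET enzymes form both bases, and TDG, a DNA glycosylase, excises them. The design held 2 whole-genome libraries of wild-type cells and 2 reduced-representation libraries, 1 with a control shRNA and 1 with an shRNA against Tdg. The first whole-genome library listed 331875 CpGs and the second 118502 cytosines, of which 59265 lay on the plus and 59237 on the minus strand. The control shRNA library listed 12895 and the Tdg shRNA library 8948 cytosines. All 4 lists were the authors' own calls. The labels do not say whether the whole-genome libraries came from separate cultures. Read depth could be recovered from the p-values of the second whole-genome library alone. There, listed sites had a median of 13 reads (quartiles 11 and 19) and at least 10, with at least 3 converted. The commonest combination, 3 converted of 10 reads, has an exact 95% interval of 6.67% to 65.2%, so that the level of a single site was poorly determined in this library.

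Most CpGs listed in the first whole-genome library of wild-type cells had a low level. The level does not tell 5fC or 5caC from cytosines that escaped the enzyme beyond the background. The median level in the first whole-genome library was 11.1% after the authors' background correction, with quartiles of 5.36% and 19.4%. At the upper end, 4884 CpGs, 1.47% of the list (95% interval 1.43% to 1.51%), were at 100%. At the lower end, 66550 CpGs, 20.1% (19.9% to 20.2%), were listed at 0, and the median of the remainder was 13.7%. Of the 6789 CpGs in this list that the second library called on the minus strand only, 69.5% were at 0. The control shRNA library had a median of 9.89% and the Tdg shRNA library of 12.5%, and neither listed a site at 0. In the second whole-genome library, the median fraction of converted reads at sites with recovered reads was 27.3% before any correction. This value leaves out its strongest sites. It is also bounded below by the calls, which held at least 3 converted reads (median 4) among a median of 13 reads.

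Few CpGs had both strands listed. The median distance from one listed site to the next was 1108 bp in the first and 4487 bp in the second whole-genome library, and 30.3% and 24.8% of sites had the next one within 100 bp. In the sparser control and Tdg shRNA libraries the median distances were 57141 bp and 83252.5 bp, with 14.3% and 15.1% within 100 bp. No distance for randomly placed CpGs was computed. In the second library, which listed each strand separately, both cytosines were listed at 899 CpGs, so that 1.52% of sites (1.45% to 1.59%) had their partner listed. In the control shRNA library 14 CpGs and in the Tdg shRNA library 174 CpGs had both strands listed, or 0.217% (0.144% to 0.314%) and 3.89% (3.50% to 4.31%) of sites. Coverage of the partner cytosine is unknown, so the absence of a partner does not show that it was unmodified.

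The 2 whole-genome libraries shared a part of their sites, and more so where the evidence was stronger. Of the plus-strand sites of the second library, 20901 or 35.3% (34.9% to 35.7%) were listed in the first at the same base. Within 100 bp, 60.5% had a neighbour in the first list. The overlap that chance gives among covered CpGs was not computed, because coverage is unknown. The share at the same base was 22.6% among plus-strand sites with p-values of 0.005 to 0.01 and 70.1% (68.9% to 71.2%) among those at or below 1e-12. It was 22.4% at sites with 10 reads and 44.5% at sites with 31 reads or more. Minus-strand sites of the second library fell on a listed CpG of the first in 12.5% of cases (12.2% to 12.7%). In the other direction, 8.34% of the CpGs of the first list were listed in the second on either strand. At the 15117 shared plus-strand sites with recovered reads, Spearman's rho of uncorrected levels was 0.23 across sites, which are not independent replicates. Reads were not recovered for 27.6% of the 20901 shared sites, those with p-values at or below 1e-07. Leaving these out caps the level of the second library, most of all at deep sites, so neither rho nor the medians describe all shared sites. The median was 15.8% in the first and 27.3% in the second library, where 83.3% of these sites were higher. Listing in the second library needed at least 3 converted reads, which keeps out low levels at sites with few reads and raises its median. With at least 20 reads in the second library, 71.5% of sites were higher in it. At the 797 of these sites with at least 50 reads in the second library, the medians were 13.9% and 12.3%, and 43.7% were higher in the second.

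**Figure D1:**
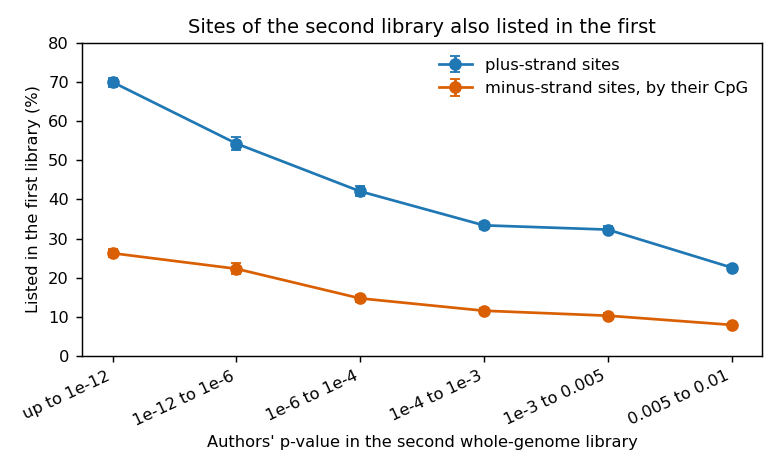
Share of sites of the second whole-genome library that were also listed in the first (y axis, %), by the authors' p-value in the second library (x axis), for plus-strand sites matched by base and minus-strand sites matched by their CpG. Points are shares and bars exact 95% intervals; the plus-strand share is 70.1% at the smallest p-values and 22.6% at the largest.

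The X chromosome held far fewer listed sites than the autosomes in whole-genome libraries. In the first library, X had 18.7 and the autosomes together 132.0 sites per Mb, a ratio of 0.142 (95% interval 0.137 to 0.147). In the second, the values were 8.80 and 46.5 per Mb, a ratio of 0.190 (0.180 to 0.199). No autosome was below 85.7 sites per Mb (chromosome 3) in the first or 32.8 (chromosome 3) in the second. The reduced-representation libraries had ratios of 0.453 (0.409 to 0.501) with control shRNA and 0.459 (0.405 to 0.518) with Tdg shRNA. Chromosome 11 was the densest autosome in the first library with 192.7 sites per Mb and in the second with 67.8. These densities are not corrected for the number of CpGs, for coverage or for copy number.

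Sequence around the CpG was deposited for the first whole-genome library alone. The most frequent of the 64 possible contexts was TGCGT with 12694 sites, 3.82% of the list. These sites had a median level of 18.1%, and of 20.5% without those at 0, the highest of all contexts. CACGC was listed 10229 times with a median level of 1.86%, since 47.9% of these sites (47.0% to 48.9%) were at 0. The share at 0 differed between a sequence and its reverse complement. It was 35.0% for ACGC and 11.6% for GCGT, and 28.0% for TCGC and 15.2% for GCGA. The other pairs were CCGC with 26.4% and GCGG with 18.6%, TCGT with 21.04% and ACGA with 16.7%, CCGT with 20.2% and ACGG with 17.3%, and CCGA with 19.5% and TCGG with 17.9%. Contexts that equal their own reverse complement had 16.2% for TCGA, 18.2% for ACGT, 18.9% for CCGG and 22.8% for GCGC. How often each context occurs in the genome was not used here, so these counts are not enrichments.

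**Figure D2:**
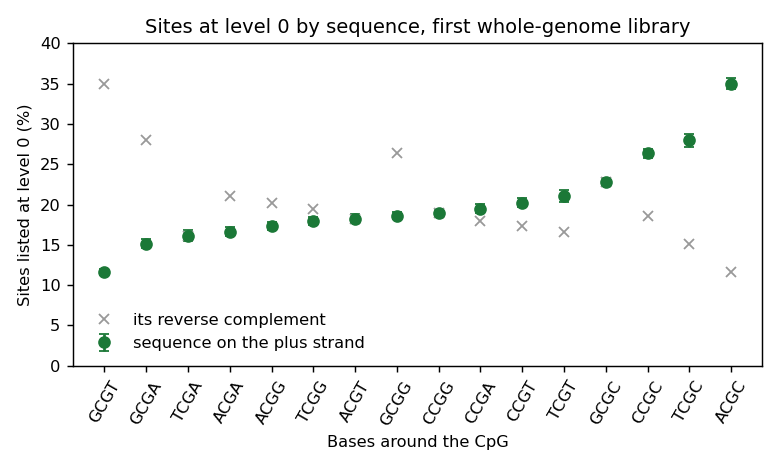
Share of CpGs listed at level 0 in the first whole-genome library (y axis, %) for each sequence of 4 bases around the CpG (x axis), with exact 95% intervals; crosses give the share for the reverse complement. GCGT is lowest at 11.6% and its reverse complement ACGC highest at 35.0%.

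The windows of 10 kb with the most sites in both whole-genome libraries were mostly on unplaced sequence. The first 4 lay on the unplaced contigs of mm9 (chrUn_random), at positions 3910001 to 3920000 with 65 shared sites, 5810001 to 5820000 with 58, 5480001 to 5490000 with 52 and 3560001 to 3570000 with 48. The fifth, on chromosome 12 from 3350001 to 3360000, had 46. By comparison, a window that held any site had a median of 2 sites in the first and 1 in the second library. What the annotation places in these windows was not analysed here.

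The comparison of Tdg shRNA with control shRNA addresses how the listed sites differ when TDG, which excises 5fC and 5caC, is depleted. The extent of the depletion was not analysed here. The Tdg shRNA library listed fewer sites, 8948 against 12895, a ratio of 0.694 (95% interval 0.675 to 0.713), and the ratio was lowest for sites of low level. Below a level of 5% the libraries listed 430 and 2054 sites, a ratio of 0.209 (0.188 to 0.232). From 5% to 10% the ratio was 0.580 (0.552 to 0.609). From 10% to 20% there were 3982 sites with Tdg shRNA and 4212 with control shRNA, a ratio of 0.945 (0.905 to 0.987). From 20% to 50% there were 882 and 1142, a ratio of 0.772 (0.707 to 0.844). From 50% to 90% there were 347 and 295 sites, a ratio of 1.18 (1.00 to 1.38), and at 90% or more 684 and 669, a ratio of 1.02 (0.918 to 1.14). Each group was 1 library, so there is no replicate check and the intervals hold counting error only. The depth of both is unknown, and a lower depth also removes sites of low level. The lowest uncorrected level listed was 3.80% with Tdg shRNA and 3.13% with control shRNA.

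**Figure D3:**
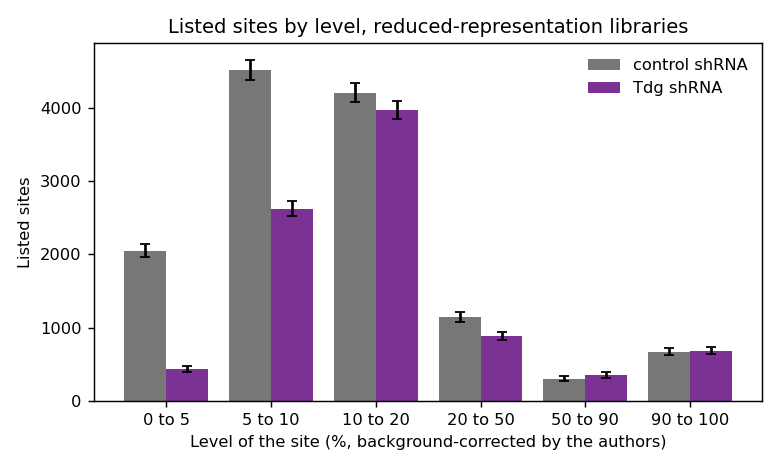
Number of listed cytosines (y axis) by background-corrected level (x axis, %) in the control shRNA and Tdg shRNA libraries, 1 library each. Bars are counts with exact Poisson 95% intervals; the libraries differ most below 10%, with 430 against 2054 sites in the lowest class.

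The shRNA libraries shared 1567 sites, 17.5% (16.7% to 18.3%) of the Tdg shRNA list and 12.2% (11.6% to 12.7%) of the control list. Within 1 kb, 46.6% of Tdg shRNA sites had a control site. Both libraries can hold sites on MspI fragments only, and the overlap that chance gives on these was not computed. A larger share was common to both at high levels. Of control sites below 5%, 3.99% were listed with Tdg shRNA, and of those at 90% or more, 73.4% (69.9% to 76.7%). Of Tdg shRNA sites, 63.9% (60.2% to 67.5%) at 90% or more were listed with control shRNA. At low levels this share did not rise steadily, with 17.0% (13.5% to 20.9%) below 5%, 9.95% from 5% to 10% and 9.44% from 10% to 20%. Levels at shared sites ranked alike (Spearman's rho 0.89 across all shared sites and 0.68 across those below 90% in both libraries, and sites are not independent replicates). They were lower with Tdg shRNA at 802 sites, higher at 473 and equal at 292. The median difference of Tdg minus control shRNA was -0.18 percentage points (-0.87 to 0), a value held near 0 by the 292 ties. Without ties, at the 1275 sites below 100% in at least 1 library, it was -2.60 points (-3.13 to -1.98), and 62.9% of sites (60.2% to 65.6%) were lower with Tdg shRNA. Among the 1058 shared sites below 90% in both libraries, a subset chosen after the levels were seen, 61.2% (58.1% to 64.1%) were lower with Tdg shRNA, and the median difference was -2.48 points (-3.22 to -1.65). Sites with a mean level of 50% to 70% had the largest median difference, -18.1 points (-29.0 to -5.87) over 98 sites, with medians of 51.8% with Tdg shRNA and 69.8% with control shRNA. Those with a mean below 10% had 0.31 points (-0.17 to 0.95) over 268 sites.

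**Figure D4:**
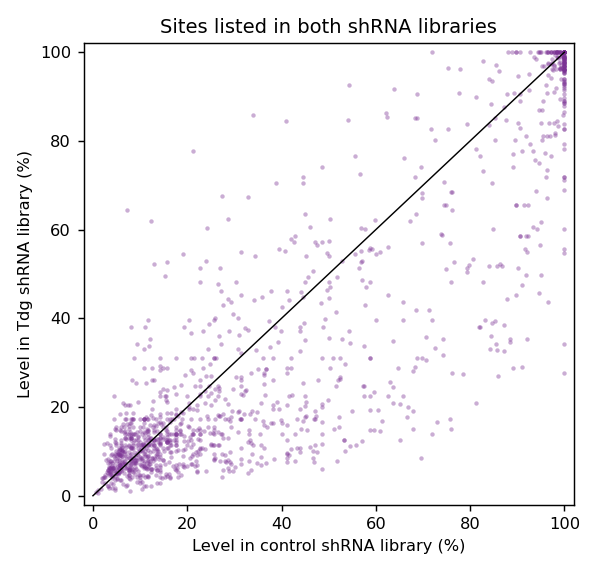
Background-corrected level of each of the 1567 cytosines listed in both shRNA libraries, with control shRNA on the x axis and Tdg shRNA on the y axis (both %). The line marks equal levels; 802 points lie below it and 473 above.

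The largest gains of sites with Tdg shRNA lay on chromosomes 9 and 2. The 5 windows of 10 kb with the largest gain were 4 consecutive windows at the start of chromosome 9, from 3000001 to 3040000, and 1 on chromosome 2, from 98500001 to 98510000. On chromosome 9 from 3020001 to 3030000 the Tdg shRNA library listed 119 sites (98.6 to 142.4) and the control library 17 (9.90 to 27.2). From 3000001 to 3010000 the counts were 100 and 10, from 3030001 to 3040000 84 and 17, and from 3010001 to 3020000 49 and 7. The window on chromosome 2 had 72 and 22 sites. In the second whole-genome library these windows had median recovered depths of 122 to 700 reads, against 13 over all sites. The 5 largest losses were small. Chromosome 14 from 122870001 to 122880000 had 8 control sites and 1 with Tdg shRNA, chromosome 1 from 42750001 to 42760000 and chromosome 10 from 119910001 to 119920000 had 7 and 1 each, and chromosome 11 from 97390001 to 97400000 and chromosome 12 from 60160001 to 60170000 had 6 and 0. The count of 0 allows up to 3.69 sites. Over the 13049 windows with a site in either library, 4078 held more sites with Tdg shRNA, 7224 held more with control shRNA and 1747 held as many in both. A gain of at least 5 sites was found in 34 windows and a loss of at least 5 in 31. Of the windows with such a gain, 21 were dense windows or lay on unplaced contigs. The losses were not split in this way. In the 12 dense windows together, the counts were 481 and 97, a ratio of 4.96 (3.98 to 6.23), and outside them 8467 and 12798, a ratio of 0.662 (0.644 to 0.680). Most of the dense-window sites came from the 3 dense windows on chromosome 9, with 303 against 44, and the window on chromosome 2. The 7 on unplaced contigs held 81 and 1, with no site in either library in 1 of them, and the window on chromosome 17 held 25 and 30, a ratio of 0.833 (0.470 to 1.47). Levels at the 73 shared sites inside dense windows were lower with Tdg shRNA at 53 sites, with a median difference of -4.03 points (-7.08 to -1.95).

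Few sites of the reduced-representation libraries were listed in whole-genome DNA at the same base, and more had a listed site nearby. At the same base, 4.92% (4.56% to 5.31%) of control shRNA sites and 14.9% (14.2% to 15.7%) of Tdg shRNA sites were listed in at least 1 whole-genome library. The second whole-genome library held 2.33% of control and 11.7% of Tdg shRNA sites, and the first, which gave the plus strand only, 3.20% and 7.02%. Outside dense windows the shares in either library were 4.38% and 10.6%. With both strands of a CpG merged, since the strand of shRNA library positions is unknown, they were 8.45% and 19.3%. Within 100 bp they were 46.5% and 53.6%. The assays select different fragments and the cells differed by the shRNA, so these shares do not measure replication of a call.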

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

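The tests in this part were all chosen after the results were seen. Unplaced contigs (chrUn_random) held 2.86% of the sites of the Tdg shRNA library and 0.101% of those of the control shRNA library, or 256 sites (95% interval 225.6 to 289.4) against 13 (6.92 to 22.2). The share drew attention because it lay above that of the control library on sequence that the comparison of the chromosomes leaves aside. The whole-genome libraries of wild-type cells held 0.555% and 1.64% of their sites there.

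Of the sites on unplaced contigs, 81 with Tdg shRNA and 1 with control shRNA lay in dense windows and 175 and 12 outside them, where no explanation was tested. The 12 dense windows, most of whose shRNA library sites lay on chromosomes 9 and 2, together held more sites with Tdg shRNA than with control shRNA. More reads or easier calling over the whole Tdg shRNA library would also add sites outside these windows. There that library listed fewer sites, at a ratio of 0.662, which argues against this as the only difference between the libraries. The number of listed sites also depends on their levels, and the depth of both shRNA libraries is unknown. The ratio therefore cannot decide which library had more reads. Many copies of a sequence aligned to few reference positions were weighed as the source of the density of sites in dense windows. In the 5 on chromosomes 2, 9 and 17 the recovered depth of the second whole-genome library was 17.5 times that elsewhere (median 227 against 13 reads). This met the 3 times set as the bar for this explanation. In the 7 on unplaced contigs the depth was 2.46 times that elsewhere (median 32), below this bar and above the 1.5 times that would count against it. The windows were themselves chosen by the number of sites listed in this library, and low levels were listed only at deeper sites. The choice thus favours high depth, so the depth cannot decide and the explanation stays open in both parts. Reads were recovered at 231 of 681 and 171 of 455 sites of these windows, since 64.2% of dense-window sites had p-values at or below 1e-07 against 14.2% elsewhere, so both depth ratios leave out most of these sites. Both shRNA libraries come from the same cell line, so such copies would explain the difference only if the share of repeat-derived fragments also differed between them, which the files do not show. An effect of Tdg knockdown on repeated DNA, with a ratio of 4.96 in the windows, cannot be told apart from a difference between 2 single libraries, because each group has 1.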

How the results depend on the processing

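All alternatives without dense windows, without sites at 0, at a level of 20% or more, below 90%, below 100% in at least 1 library or with uncorrected fractions, and autosomes only for level differences, were chosen after the data were seen. Of 75 alternative values, 36 stayed within 1.5 times the reported count or inside its interval, and 39 moved out of it. A change of direction could be registered for the ratio of Tdg to control sites alone, where 0 were found. The interval of the level difference over all shared sites reached 0, so no direction was assigned to it. Keeping the stricter part of each list by the authors' value left 165696 sites in the first and 58062 in the second whole-genome library, 6319 with control and 4187 with Tdg shRNA, by construction, with medians of 19.4%, 33.3% (uncorrected), 15.7% and 18.0%. Without sites at 0 the median of the first library was 13.7%, and on autosomes that of the Tdg shRNA library was 12.3%. Overlap of the whole-genome libraries was 23.5% with strands merged, 40.5% within 10 bp and 60.5% within 100 bp. The ratio of Tdg to control sites was 0.694 for all sites, 0.982 above the pooled median level, 0.997 in windows of 1 kb with a site in both, 0.908 at levels of 20% or more, 0.674 on autosomes and 0.662 without dense windows. Of Tdg shRNA sites, 19.95% were shared above the pooled median, 42.6% in windows with a site in both and 42.3% (809 sites) at 20% or more. The windows of 1 kb were kept for holding a site in both lists. This choice draws their ratio toward 1 and raises their shared share by construction, so neither value shows equal numbers of sites at equal coverage. Over all shared sites the median level difference of -0.18 points and the 51.2% of sites lower with Tdg shRNA became 0 and 49.2% with uncorrected fractions, -0.03 and 50.1% without dense windows and -0.35 and 51.9% on autosomes. Below 90% the median level difference was -2.48 points, or -2.07 with uncorrected fractions, and 61.2% or 58.3% of sites were lower with Tdg shRNA. Below 100% in at least 1 library the values were -2.60 points and 62.9%. Control and Tdg shRNA sites were listed in whole-genome libraries at 8.45% and 19.3% with strands merged, 46.5% and 53.6% within 100 bp, and 4.38% and 10.6% without dense windows. Leaving out each whole-genome library in turn gave 2.33% to 3.20% and 7.02% to 11.7%. On autosomes 1.26% of sites of the second library had both strands listed. No paired analysis was possible because the shRNA groups have 1 library each. Alternatives that need coverage, a genome, an annotation or gene lists could not be run without them. With a median of 13 reads at listed sites of the second library and at least 3 converted, low levels were detectable only at deeper sites.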

Other observations

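The tests in this part were all chosen after the results were seen. Chromosome 1 stood apart in the first whole-genome library. It held 29040 sites against 6981 in the second library, a ratio of 4.16, and the other autosomes had ratios of 2.49 to 3.10. Its sites had a median level of 14.1%, against 10% to 11.6% on the other autosomes, and 35.6% of them were at 20% or more, against 18.9% to 26.3%. The share of its sites listed in the second library on the plus strand was 4.23%, below the 5.28% to 6.90% of the other autosomes. This share is taken over sites of the first library, so more sites there lower it. It is therefore not separate from the ratio and does not show poorer agreement on chromosome 1. Mitochondrial DNA held 12 and 10 sites in the whole-genome libraries and 2 in each shRNA library, and 7 of those in the second library had a median recovered depth of 616 reads.

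The first whole-genome library listed 66550 CpGs at level 0. The 10 lowest steps above 0 held at most 267 sites each. A smooth low tail floored at the 3.0% background would make at most 8277 over the 31 steps up to it, too few. This bound needs fractions spread over all steps. At sites with few reads the lowest fractions above 0 cannot occur, and 0 converted reads give exactly 0. The depth of the first library is unknown, so the comparison cannot decide whether flooring made the sites at 0. A candidate explanation is that the deposited level is that of the plus strand, while the call could come from either strand. Among CpGs listed in both libraries, 69.5% (68.3% to 70.5%) of the 6789 that the second called on the minus strand only were at 0 in the first, and 2.23% (2.03% to 2.44%) of the 20297 called on the plus strand only. The differing shares at 0 of a sequence and its reverse complement are consistent with this, but calls on the minus strand were also less often recovered at all (12.5% against 35.3%), which stays open.

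A further pattern is the 4884 CpGs at a level of 100% in the first library. The E14 line and the reference genome come from different mouse strains, so a base variant that removes the CpG was weighed. A change of the CpG to TG or CA would make both strands read as converted. Any other single base change that removes the CpG would do so on the plus or the minus strand alone. The second library listed the plus strand at 22.8% (21.6% to 24.0%) of these CpGs and the minus strand at 2.83% (2.38% to 3.33%). This argues against changes to TG or CA as the source of most of them. It cannot decide on changes that read as converted on the plus strand alone. Alternating TG and CG repeats were weighed through 6 contexts (TGCGT, CACGC, CGCGT, TGCGC, CGCGC and CACGT). They made up 26.6% (25.4% to 27.9%) of these CpGs and 14.4% of the whole list, too few to be the source of most. CACGT does not occur in such repeats on either strand, so counting it can only raise the share. TGCGT made up 11.9% of these CpGs and 3.82% of the list. CACGC alone of the 6 was rarer among these CpGs, with 2.11% against 3.08%. Other causes, such as cytosines the enzyme did not reach, stay open, and no biological explanation was tested.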
